A study of Homo sapiens with 18 samples.

How the data were processed

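RNA was sequenced from LNCaP cells, an established human prostate cancer line, in 18 libraries. Per the labels, all cells carried a short hairpin RNA against HOXB13 with an inducible rescue by empty vector (EV), wild-type HOXB13 (WT) or HOXB13 with 3 phosphorylation sites changed to alanine (3A). Cells were kept for 48 h in medium with 2% charcoal-stripped serum, which removes steroids, and then received 0.1% ethanol (vehicle) or 10 nM R1881 for 24 h. Libraries were grouped by rescue state and treatment from the sample titles, 3 per group. The titles also give replicate numbers, and the labels do not say what a number stands for.

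The authors deposited a table of counts, whole reads per gene for 58735 Ensembl genes, and a table of FPKM values for the same genes. Per the labels' protocols, paired-end libraries were made from total RNA with a NEBNext Ultra II RNA kit and sequenced on a NovaSeq. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the build hg38. The annotation release, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Many named genes with large overlaps on either strand or with near-identical copies are therefore reported as uncertain. Other overlaps are not marked below. Examples are KRT18 (16.3% of exon bases), HMGCS1 (14.95%), IDI1 (14.8%), CLDN7 (12.3%) and CEBPB (11.8%). Where counting ignores strand, reads of overlapping genes cannot be told apart. The deposited FPKM values equalled count divided by gene length and by an effective library size to within 0.1% for 100% of 407062 values above 0, so they hold no information beyond the counts. The file has 177 gene symbols that name more than 1 gene, and named genes were followed by their Ensembl identifiers.

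The counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 17162 genes, libraries were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group was fitted to all 18 libraries (12 residual degrees of freedom, common dispersion 0.0186, prior degrees of freedom 8.75). The 12 comparisons were WT against EV, 3A against EV and 3A against WT in each treatment, R1881 against vehicle in each rescue state, and the 3 differences between those responses (interactions). P-values were adjusted by Benjamini-Hochberg over all genes tested, and an adjusted p under 0.05 was called. Standard errors of log2 fold changes come from the F statistic. Intervals are at 95%, and folds against a group with 0 counts use a floor of 3 counts per group. Reads carry no molecular identifiers, so counting intervals do not cover amplification.

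Fixed before the data were examined were 17 gene lists: androgen-induced, androgen-repressed, mitotic cell cycle, G1/S and DNA replication, sterol biosynthesis and uptake, fatty acid synthesis, glycolysis, ATF4 and amino acid response, unfolded protein response, interferon-stimulated, ribosome biogenesis, luminal epithelial, mesenchymal and migration, and neuroendocrine genes, HOXB cluster neighbours, mitochondrially encoded mRNAs and markers of other cell types. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, and with fry, with adjustment over the 17 lists of a comparison. Members were also counted with p-values adjusted over the list alone.

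Named genes were chosen by a rule fixed at the same time. HOXB13 is given throughout. For WT against EV and 3A against WT in both treatments and for R1881 against vehicle in WT, the rule took the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those called, with a mean of at least 1 CPM and every library of one group above every library of the other. For the other comparisons of 2 groups it took 5 each, for the interactions the 5 with the smallest p in each direction, and for each list up to 4 members with the smallest adjusted p. After the values had been seen, this was narrowed in the text to genes that kept their call without any 1 library, and the remaining genes of the rule are named without a value, except where their values without those libraries are given. Some genes that met the rule are not reported here, and they stay in every count and list test.

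In each library 21253 to 23377 genes were detected. The procedure was tested on simulated counts for the 17162 genes. For 3A against EV in vehicle, 24 of 67 genes changed 1.5-fold, 57 of 67 changed 2-fold and 64 of 66 changed 4-fold were recovered, with 8 false calls. For WT against EV with R1881 the numbers were 32, 57 and 62 with 7 false calls, and for the interaction of WT and EV 6, 47 and 60 with 9 false calls. A list of 20 genes raised 1.5-fold was called by camera and 0 of 16 unchanged lists were.

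The alternatives were size factors by RLE, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in 3 libraries, protein-coding genes only, a fit to only the groups compared, the replicate number as a block, limma on log2(FPKM + 1), and leaving out each library in turn. A correction for GC content and gene length, by loess with a span of 0.3 as an offset for each library, alone, with the block and, for the lists, with an estimated correlation, was added after seeing the data, as was the block with an estimated correlation. GC content and length came from GENCODE release 29 on hg38 and were found for 99.9% of the tested genes. In simulated counts for 3A against EV in vehicle, an added GC slope gave 3363 false calls without the correction and 4 with it. Replicate numbers paired the libraries where every same-numbered pair deviated together with a correlation over 0.1. This held for 3A against EV with R1881 (0.105, 0.154 and 0.107) and for R1881 against vehicle in EV (0.163, 0.198 and 0.163), a pairing seen in the data and not stated in the labels. Gene overlaps between WT and 3A against the shared EV libraries were set beside 20 simulations of unchanged groups. All samples and both deposited tables were used.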

Results

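RNA was measured in 18 libraries of LNCaP, a human prostate cancer cell line that responds to androgen. All libraries carried a short hairpin RNA against HOXB13, a homeobox transcription factor of the prostate, together with an inducible rescue by empty vector (EV), wild-type HOXB13 (WT) or HOXB13 with 3 phosphorylation sites changed to alanine (3A). Each rescue state was sampled in triplicate with ethanol (vehicle) or with 10 nM of the synthetic androgen R1881 for 24 h, which gave 6 groups of 3 libraries. Total counts ran from 22812641 to 30611980 per library, and 17162 of the 58735 genes in the file had enough counts to be tested. The first principal component held 44.9% of the variance and separated R1881 from vehicle, and the second held 10.3%. Mitochondrially encoded RNA took 2.71% to 5.70% of the counts. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 8.73 to 51.4 between libraries of one group. The labels do not say that replicates are separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Levels are given as mean CPM, scaled by library size, ± SD (n = 3). Changes are log2 fold changes ± standard error, and the median of a gene list is that of its members' log2 fold changes.

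The targeted gene was read first, since the rescue states are defined by it. HOXB13 (ENSG00000159184, chromosome 17, 48724763 to 48729178, minus strand, hg38) stood at 533 ± 33.9 CPM in the EV, 536 ± 50.2 in the WT and 759 ± 102 in the 3A vehicle libraries. With R1881 the levels were 416 ± 9.87, 347 ± 26.2 and 507 ± 71.0 CPM. HOXB13 RNA was thus not detectably higher in libraries labelled WT than in those labelled EV, in vehicle (log2 fold change 0.01, 95% interval -0.22 to 0.24, edgeR adjusted p = 0.999) or with R1881 (-0.26, -0.49 to -0.03, edgeR adjusted p = 0.143). It was higher in 3A than in EV in vehicle (0.51, edgeR adjusted p = 0.00482), and higher in 3A than in WT in vehicle (0.50, edgeR adjusted p = 0.00807) and with R1881 (0.55, edgeR adjusted p = 0.00595). Both 3A to WT calls were lost without 1 library, at 0.39 without 3A vehicle library 2 and at 0.48 without WT R1881 library 2. The 3A to EV difference with R1881 missed the threshold (0.28, edgeR adjusted p = 0.119), with adjusted p from 0.00803 to 0.403 over 16 alternatives, and passed it only with a correction for GC content and gene length chosen after seeing the data (0.38) or with that correction and a replicate block (0.38). R1881 lowered HOXB13 RNA in WT (-0.63, edgeR adjusted p = 0.000221) and 3A (-0.58, edgeR adjusted p = 0.000361). In EV the value was -0.36 (edgeR adjusted p = 0.0202), a call lost without EV vehicle library 1 (-0.33) or 3 (-0.30) or EV R1881 library 1 (-0.35), 2 (-0.32) or 3 (-0.36). Gene counts cannot separate the RNA targeted by the hairpin from the rescue RNA, or WT from 3A RNA, and no library without the hairpin was analysed here. The groups are therefore named by their labels, and neither the knockdown nor the WT rescue can be checked at the RNA level.

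**Figure D1:**
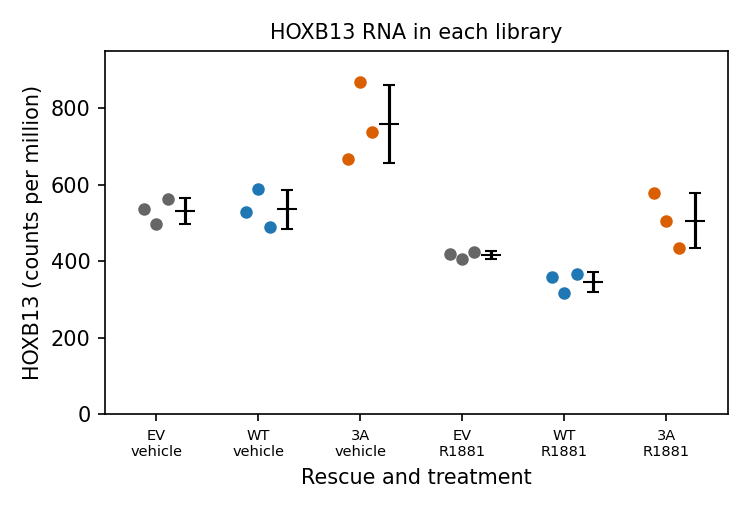
HOXB13 CPM in each of the 18 libraries (points), with the mean (horizontal mark) and SD (error bar) of the 3 libraries of each rescue state in vehicle and with R1881. The means in vehicle are 533 for EV, 536 for WT and 759 for 3A, and those with R1881 are 416, 347 and 507.

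The response to androgen was compared within each rescue state. R1881 raised androgen receptor targets in all 3 states, by amounts that differed between genes. FKBP5, a co-chaperone of steroid receptors, rose by 4.98 in EV (edgeR adjusted p = 7.78e-17), 4.35 in WT (edgeR adjusted p = 7.07e-16) and 4.58 in 3A (edgeR adjusted p = 2.81e-16) on the log2 scale. SLC45A3, a prostate transporter, rose by 4.47, 3.87 and 3.94 in the same order. KLK3, which encodes prostate-specific antigen, rose by 2.21, 2.38 and 1.98. It is outside the naming rule for these comparisons and was chosen after its values were seen. SLC2A3, a glucose transporter, had 0 counts in the EV and 3A vehicle groups and was at least 657-fold and at least 812-fold higher with R1881, against a floor of 3 counts per group. In WT it had 1 count in vehicle and 1047 with R1881, a ratio of 1050 (exact 95% interval 188 to 41500). STEAP4, a metalloreductase, rose by 10.42 in EV, and its ratios were 1230 in WT (exact 95% interval 422 to 5990) and 3540 in 3A (980 to 29200), with 3 and 2 counts in vehicle. Intervals and floors cover counting error only. CCDC141 rose by 8.09, 8.90 and 9.13. The WT group, for which more genes were named, also included F5, a coagulation factor (7.39 ± 0.36, edgeR adjusted p = 2.65e-12), CHRNA2, an acetylcholine receptor subunit (6.29 ± 0.23, edgeR adjusted p = 4.78e-14), and KL, the klotho gene (5.96 ± 0.64, edgeR adjusted p = 8.92e-07). Among the falls, ABCA1, a cholesterol efflux transporter, changed by -5.29, -4.76 and -5.87 in EV, WT and 3A. PLD1, a phospholipase, changed by -5.65, -4.99 and -4.86, and SLC6A20, an amino acid transporter, by -5.54, -4.87 and -4.80. In total 2270 genes rose and 2066 fell in EV, 1882 rose and 1568 fell in WT, and 2130 rose and 2072 fell in 3A by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Leaving out any 1 library moved none of these 3 totals by over 1.5 times. All 40 genes that the naming rule gave for the 3 comparisons kept their call without any 1 library.

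Gene lists fixed before the data were examined were then counted in EV, WT and 3A. Of 30 androgen-induced genes, 29 rose in each state, STEAP2 being the exception, and 29 when adjusted over the list alone. The list medians were 2.82, 2.38 and 2.75, the same with STEAP4 at the lower end of its interval. Camera gave adjusted p = 5.07e-07, 3.15e-07 and 6.46e-07 with an estimated correlation. Of 15 androgen-repressed genes, 9 fell in EV, 10 in WT and 11 in 3A, and as many when adjusted over the list alone. Their camera adjusted p = 0.000371, 0.000360 and 0.000338 with an estimated correlation. OPRK1, an opioid receptor, fell by 3.20 in EV, 3.55 in WT and 3.96 in 3A, and ACKR3, a chemokine scavenger receptor, fell by 2.47, 1.60 and 2.31. Against the name of that list, the steroid glucuronidation genes UGT2B28 and UGT2B11 rose in all 3 states, with UGT2B28 at 5.14 in 3A. TFPI, a coagulation inhibitor, rose in WT and 3A. The UGT2B genes resemble each other closely, so their counts are uncertain. Of 18 sterol biosynthesis and uptake genes, 18 rose in EV, 17 in WT and 16 in 3A, and 18, 17 and 17 when adjusted over the list alone. The camera adjusted p of this list was 0.000261, 0.000360 and 0.000562 with an estimated correlation. IDI1, which isomerises isopentenyl diphosphate, rose by 1.51, 1.41 and 1.57, and HMGCS1, which forms HMG-CoA, by 1.53, 1.45 and 1.44. Of 15 fatty acid synthesis genes 8, 10 and 9 rose, and 9, 10 and 10 when adjusted over the list alone. With an estimated correlation camera gave adjusted p = 0.0156, 0.00607 and 0.0278. The acyl-CoA synthetase ACSL3 rose by 3.19, 2.67 and 3.42. In 3A 2 members fell, at most 1 of them without 3A vehicle library 1, 2 or 3 or 3A R1881 library 1. Of 16 unfolded protein response genes 14, 9 and 14 rose, and 14, 10 and 14 when adjusted over the list alone. In each state 1 member was lower. In EV that call was lost (0 lower) without EV vehicle library 1 or EV R1881 library 2, and in 3A without any 3A vehicle library or without 3A R1881 library 1 or 2. This list passed with an estimated correlation in EV (camera adjusted p = 0.0207) and 3A (0.0278). In WT camera gave 0.000457 with the preset correlation and adjusted p = 0.161 with an estimated correlation. DNAJB9, an endoplasmic reticulum co-chaperone, rose by 1.09, 0.79 and 1.47. Of 22 genes of G1/S and DNA replication 9 rose and 1 fell in EV, and 11 and 1 when adjusted over the list alone (median 0.35, camera adjusted p = 0.0180, adjusted p = 0.520 with an estimated correlation), 18 rose in WT, and 20 when adjusted over the list alone (median 0.64, camera adjusted p = 1.96e-10, adjusted p = 0.161 with an estimated correlation), and 3 rose in 3A, and 3 when adjusted over the list alone (median 0.19, camera adjusted p = 0.212, adjusted p = 0.784 with an estimated correlation). The preset call in EV ended without EV vehicle library 2 (camera adjusted p = 0.0523, with 6 higher and 0 lower) or EV R1881 library 1 (0.0863, with 5 higher). Of 20 ATF4 and amino acid response genes 10 fell and 1 rose in EV, and 11 and 1 when adjusted over the list alone (median -0.34, camera adjusted p = 0.00683, adjusted p = 0.436 with an estimated correlation). In WT 11 fell and 1 rose, and 12 and 1 when adjusted over the list alone (median -0.37, camera adjusted p = 0.000153, adjusted p = 0.236 with an estimated correlation), and in 3A 5 fell and 2 rose, and 8 and 2 when adjusted over the list alone (median -0.21, camera adjusted p = 0.0577, adjusted p = 0.621 with an estimated correlation). The number that fell in EV was 4, 6 and 4 without EV vehicle libraries 1 and 3 and EV R1881 library 2, and in WT it was 6, 7, 6 and 5 without WT vehicle libraries 2 and 3 and WT R1881 libraries 1 and 2. In 3A the list passed without 3A vehicle library 3 (camera adjusted p = 0.00981) or 3A R1881 library 1 (0.0261).

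In vehicle, the question was which genes differ when the rescue carries wild-type HOXB13 in place of the empty vector. BVES, a Popeye domain protein of the cell membrane that binds cAMP (ENSG00000112276, chromosome 6, 105096822 to 105137174), rose from 2.39 ± 0.996 to 91.0 ± 22.6 CPM (5.27 ± 0.28, edgeR adjusted p = 2.05e-10). Its neighbour PREP, a prolyl peptidase, rose from 54.6 ± 2.25 to 171.9 ± 28.1 CPM (1.65 ± 0.11, edgeR adjusted p = 3.88e-09). PREP is outside the naming rule for this comparison and was chosen for it after its values were seen. POPDC3, the Popeye gene between them, rose by 2.37 ± 0.44, edgeR adjusted p = 0.00762. AOC1, a diamine oxidase, rose by 3.82 ± 0.33, edgeR adjusted p = 4.48e-07. CD274, which encodes the immune checkpoint ligand PD-L1, rose by 2.85 ± 0.22, edgeR adjusted p = 7.90e-08, and OR51E2, an olfactory receptor of the prostate, by 2.67 ± 0.43, edgeR adjusted p = 0.00185. Further rises were CORIN, a natriuretic peptide protease (2.55, edgeR adjusted p = 0.00185), and the growth factor TGFB3 (2.23, edgeR adjusted p = 0.00455). The kainate receptor GRIK1 (2.11, edgeR adjusted p = 0.00190) and the synaptic organiser CBLN2 (1.94, edgeR adjusted p = 3.88e-09) rose as well. CAMK2N1, an inhibitor of CaM kinase II, fell from 142 ± 17.7 to 34.7 ± 5.04 CPM (-2.04 ± 0.28, edgeR adjusted p = 0.000445). In all, 111 genes were higher and 21 lower in WT by edgeR's quasi-likelihood test, and 1265 had an unadjusted p under 0.05. Of the 20 genes that the naming rule gave, 9 kept their call without any 1 library. Those that did not included EMP1, GLP1R, SYT4, ADA2, DIO3, GSTA1 and TNFSF15, and also POPDC3, KLK2 and KLK3. POPDC3 was at 2.25 without EV vehicle library 3 and 1.99 without WT vehicle library 2. The kallikreins KLK3 (-0.93 ± 0.21, edgeR adjusted p = 0.0323) and KLK2 (-0.93 ± 0.19, edgeR adjusted p = 0.0141), both androgen-induced, were lower in WT. KLK3 was at -0.71 without EV vehicle library 3, -0.75 without WT vehicle library 1 and -0.83 without WT vehicle library 2. KLK2 was at -0.82, -0.92, -0.90 and -0.83 without EV vehicle libraries 2 and 3 and WT vehicle libraries 1 and 2, in that order. KLK4 (-0.47, edgeR adjusted p = 0.0118) lost its call without the same 4 libraries. These 3 were the members called of 30 androgen-induced genes, and 3 were called when adjusted over the list alone (median -0.02, camera adjusted p = 0.0128, adjusted p = 0.424 with an estimated correlation), and with a correction for GC content and gene length the median was -0.05. The list's preset call ended without WT vehicle library 3 (camera adjusted p = 0.392), and its count was 1 without EV vehicle library 2 and 0 without EV vehicle library 3 or WT vehicle library 1 or 2. Of 20 mitotic cell cycle genes 0 were called by edgeR, with 14 higher at an unadjusted p under 0.05 and 1 by DESeq2. Adjusted over the list alone 11 were higher (median 0.46, camera adjusted p = 4.25e-15, adjusted p = 0.249 with an estimated correlation). For G1/S and DNA replication genes 0 of 22 were called by edgeR, with 15 higher at an unadjusted p under 0.05 and 2 by DESeq2. Adjusted over the list alone 3 were higher (median 0.33, camera adjusted p = 1.99e-12, adjusted p = 0.249 with an estimated correlation). The total of 132 became 83 without EV vehicle library 2, 69 without EV vehicle library 3 and 66 without WT vehicle library 2.

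**Figure D2:**
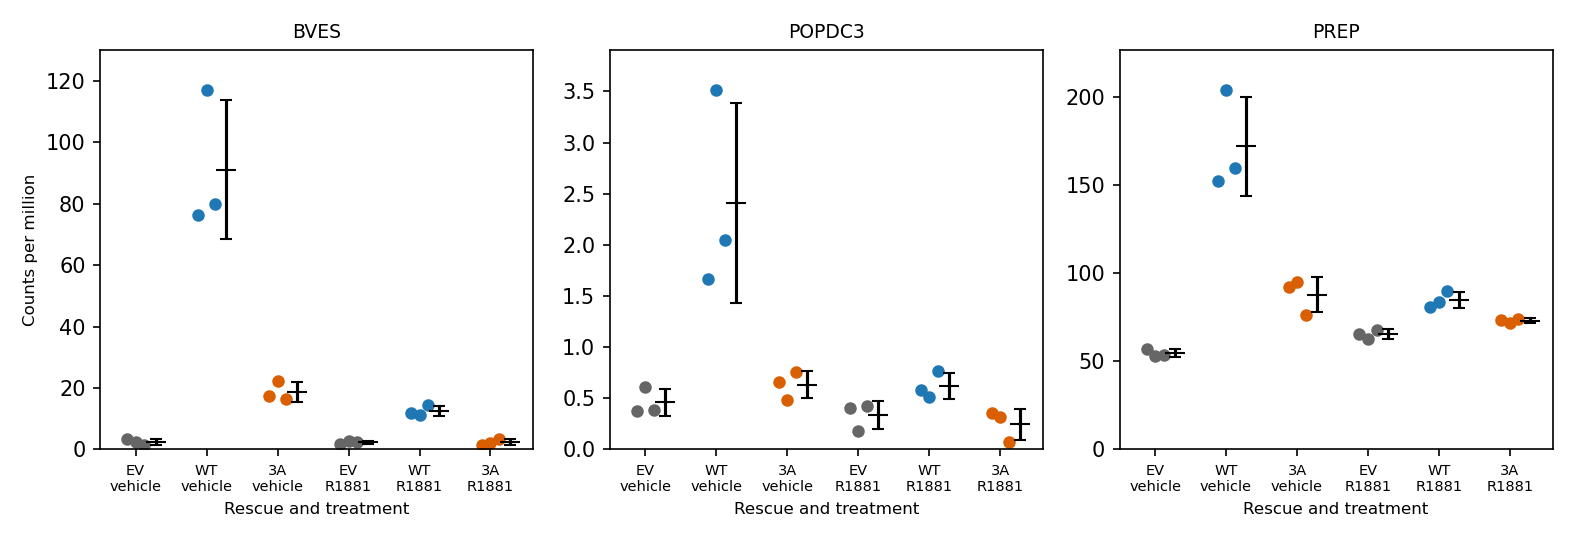
CPM of BVES, POPDC3 and PREP, neighbours on chromosome 6, in each library (points), with the mean (horizontal mark) and SD (error bar) of each group of 3. BVES stands at 91.0 in WT vehicle, 18.6 in 3A vehicle and 12.6 in WT R1881, and between 2.35 and 2.39 in EV vehicle, EV R1881 and 3A R1881.

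With R1881, 799 genes were higher and 694 lower in WT than in EV by edgeR. CBLN2 stood at 2.03 ± 0.0825 CPM in EV and 23.1 ± 0.704 in WT (3.50 ± 0.15, edgeR adjusted p = 6.32e-12). OR51E2 (3.62 ± 0.51, edgeR adjusted p = 0.000187), AOC1 (3.52 ± 0.39, edgeR adjusted p = 9.69e-06) and GRIK1 (3.32 ± 0.42, edgeR adjusted p = 5.07e-05) were again higher in WT. So were CD274 (2.80 ± 0.22, edgeR adjusted p = 1.35e-07) and BVES (2.42 ± 0.27, edgeR adjusted p = 1.56e-05). PTPRR, a phosphatase that acts on MAP kinases, rose by 2.52 ± 0.18, edgeR adjusted p = 2.00e-08. BMX, a Tec family kinase, rose by 2.32, edgeR adjusted p = 0.000290, and MAN1A1, a Golgi mannosidase, by 2.19, edgeR adjusted p = 2.63e-05. Among the falls were MICAL1, an actin-oxidising enzyme (-1.38, edgeR adjusted p = 0.000129), and PGC, the pepsinogen C gene (-1.36, edgeR adjusted p = 0.00183). SPDEF, an ETS transcription factor of luminal epithelium, went from 558 ± 48.3 to 251 ± 13.3 CPM (-1.15 ± 0.10, edgeR adjusted p = 4.58e-07). Of 22 G1/S and DNA replication genes 21 were higher in WT, and 22 when adjusted over the list alone (median 0.71, camera adjusted p = 7.74e-24, adjusted p = 0.0653 with an estimated correlation). They include MCM4, a subunit of the replicative helicase (0.88), and UHRF1, a reader of hemimethylated DNA (0.83, edgeR adjusted p = 0.000444). Of 20 mitotic genes 11 were higher, and 15 when adjusted over the list alone (median 0.67, camera adjusted p = 8.92e-15, adjusted p = 0.114 with an estimated correlation), with the kinesin KIF11 at 0.85, edgeR adjusted p = 0.000254 and MKI67 at 0.91. Without EV R1881 library 2 the G1/S and mitotic counts were 10 and 6. Of 30 androgen-induced genes 11 were lower in WT, and adjusted over the list alone 15 were lower and 1 higher (median -0.31, camera adjusted p = 3.19e-08, adjusted p = 0.0667 with an estimated correlation). FKBP5 (-0.63, edgeR adjusted p = 0.00115) and SLC45A3 (-0.55, edgeR adjusted p = 0.00116) were among them, and the count was 6 without EV R1881 library 2 and 7 without WT R1881 library 2. Of 16 unfolded protein response genes 7 were lower, and adjusted over the list alone 9 were lower and 1 higher (median -0.34, camera adjusted p = 7.53e-07, adjusted p = 0.0667 with an estimated correlation). CALR, the calreticulin gene, was at -0.45, and 3 members were lower without EV R1881 library 3 or WT R1881 library 1. Of 15 luminal epithelial genes 4 were lower and 1 higher, and 4 and 1 when adjusted over the list alone (median -0.15, camera adjusted p = 0.000765, adjusted p = 0.0489 with an estimated correlation). With a correction for GC content and gene length the median of this list was -0.05 (camera adjusted p = 0.00229, adjusted p = 0.0179 with an estimated correlation), and androgen-induced, G1/S and unfolded protein response genes then also passed with an estimated correlation (adjusted p = 0.0179 for each). The keratins KRT8 (-0.95, edgeR adjusted p = 2.85e-05) and KRT18 (-0.86, edgeR adjusted p = 0.000403) were lower. With an estimated correlation this call ended without EV R1881 library 2 (adjusted p = 0.0761), WT R1881 library 1 (adjusted p = 0.0515) or WT R1881 library 3 (adjusted p = 0.0964). Of 18 sterol genes 3 were lower, and 4 when adjusted over the list alone (median -0.18, camera adjusted p = 0.000765, adjusted p = 0.114 with an estimated correlation). The sterol count was 1 without EV R1881 library 2 or 3 or WT R1881 library 1. Leaving out 1 library also brought lists past the threshold with an estimated correlation. This was so for G1/S genes without EV R1881 library 1 (adjusted p = 0.0436) or 3 (0.0392) or WT R1881 library 2 (0.0396), and for mitotic genes without WT R1881 library 2 (0.0495). Androgen-induced genes passed without EV R1881 library 3 (0.0392) or WT R1881 library 2 (0.0493), and sterol genes without EV R1881 library 1 (0.044). Unfolded protein response genes passed without EV R1881 library 1 (0.0494) or 3 (0.0392) or WT R1881 library 2 (0.0493). With a replicate block, androgen-induced and G1/S genes passed by camera with an estimated correlation (adjusted p = 0.0202 for each). Unfolded protein response genes (0.0606) and mitotic and sterol genes (0.114 for each) did not. Of 20 named genes 16 kept their call without any 1 library (not KRT14, HSPA1A, CHST2 and B3GAT1). The remaining named falls NBL1, TAF10, PSENEN and EVA1B share exons or near-identical sequence with other genes and are uncertain. The total of 1493 was 657 without EV R1881 library 2, 677 without EV R1881 library 3, 775 without WT R1881 library 1 and 601 without WT R1881 library 2. Fold changes here followed the GC content of the genes (Spearman's rho -0.486 across 13844 genes, which are not independent replicates). With a correction for GC content and gene length 846 of the 1493 genes kept their call, and with that correction and a replicate block 843 genes were higher and 1097 lower.

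The 3A rescue was compared with the empty vector in the same way. In vehicle, 682 genes were higher and 562 lower in 3A by edgeR. BVES was higher, at 18.6 ± 3.20 CPM (2.98 ± 0.27, edgeR adjusted p = 8.27e-07), and CLSPN, the claspin adaptor of the replication checkpoint, rose by 2.22 ± 0.24, edgeR adjusted p = 2.30e-06. The largest falls that did not depend on any 1 library were KLHDC7B (-3.03, edgeR adjusted p = 0.000857), the chemerin receptor GPR1 (-2.75, edgeR adjusted p = 0.00155) and C1orf158 (-2.72, edgeR adjusted p = 1.68e-05). LCN2, a lipocalin that binds siderophores, fell as well (-2.38 ± 0.33, edgeR adjusted p = 5.31e-05). All 20 mitotic cell cycle genes were higher in 3A, and 20 when adjusted over the list alone (median 1.34, camera adjusted p = 2.39e-57, adjusted p = 0.00223 with an estimated correlation). They include MKI67, a proliferation marker (1.63 ± 0.16, edgeR adjusted p = 1.16e-06), TOP2A, a topoisomerase (1.51), and the centromere protein CENPF (1.46). Of 22 G1/S and DNA replication genes 21 were higher, and 22 when adjusted over the list alone (median 1.18, camera adjusted p = 3.72e-57, adjusted p = 0.00223 with an estimated correlation). The replication licensing factor CDC6 was at 1.41 ± 0.15, edgeR adjusted p = 2.17e-06, and UHRF1 at 1.39. ATF4 and amino acid response genes went the other way, with 17 of 20 lower, and 19 when adjusted over the list alone (median -0.91, camera adjusted p = 7.76e-45, adjusted p = 0.00223 with an estimated correlation). TRIB3, a pseudokinase induced by ATF4, fell by 1.47 ± 0.11, edgeR adjusted p = 2.67e-07. CEBPB, a bZIP transcription factor, fell by 1.39, edgeR adjusted p = 6.89e-07, and SLC7A11, the cystine transporter, fell by 1.05, edgeR adjusted p = 2.26e-06. Unfolded protein response genes were mixed, with 4 lower and 1 higher of 16, and 5 and 2 when adjusted over the list alone (median -0.08, camera adjusted p = 0.0483, adjusted p = 0.351 with an estimated correlation). HERPUD1 (-0.96, edgeR adjusted p = 1.59e-06) and XBP1 (-0.52, edgeR adjusted p = 0.000963) were lower, and MANF (0.60, edgeR adjusted p = 0.000526) was higher. The preset call of that list ended without EV vehicle library 1 (camera adjusted p = 0.0741), 3A vehicle library 2 (0.158) or 3A vehicle library 3 (0.112, with 2 members lower). Of 10 named genes 8 kept their call without any 1 library (not HTR5A and GAGE13). ZNF724 and ALDOA, also named as rises, share over 40% of their exon bases with other genes and are uncertain. The total of 1244 was 751 without EV vehicle library 3 and 805 without 3A vehicle library 2.

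With R1881, 754 genes were higher and 697 lower in 3A than in EV by edgeR. CBLN2 was higher in 3A (2.47 ± 0.16, edgeR adjusted p = 8.04e-09), as were ASB2, a subunit of ubiquitin ligases (2.12, edgeR adjusted p = 0.00164), and the reductase DHRS2 (2.10, edgeR adjusted p = 0.00166). LPO, the lactoperoxidase gene, fell by 2.62 ± 0.29, edgeR adjusted p = 5.96e-06, and BCL11B, a zinc finger transcription factor, fell by 2.42 ± 0.32, edgeR adjusted p = 3.81e-05. DMGDH, the mitochondrial dimethylglycine dehydrogenase, fell by 2.19, edgeR adjusted p = 6.38e-05, and the calcium-binding protein gene S100P fell by 1.99, edgeR adjusted p = 1.14e-05. Of 20 mitotic genes 20 were higher, and 20 when adjusted over the list alone (median 1.28, camera adjusted p = 2.72e-50, adjusted p = 0.00533 with an estimated correlation). Of 22 G1/S genes 22 were higher, and 22 when adjusted over the list alone (median 0.98, camera adjusted p = 7.77e-44, adjusted p = 0.00533 with an estimated correlation). Examples are KIF11 (1.41, edgeR adjusted p = 8.24e-07), the kinetochore motor CENPE (1.54) and MCM4 (1.11). ATF4 and amino acid response genes were lower in 17 of 20 cases, and in 18 when adjusted over the list alone (median -0.81, camera adjusted p = 1.44e-37, adjusted p = 0.00533 with an estimated correlation). TRIB3 was at -1.43, edgeR adjusted p = 1.52e-07, and SESN2, a sestrin, at -1.18, edgeR adjusted p = 1.59e-06. Luminal epithelial genes were lower in 3 of 15 cases, including CLDN7, a claudin (-0.65, edgeR adjusted p = 0.000236), and ESRP1, a splicing factor of epithelia (-0.46, edgeR adjusted p = 0.00232). Adjusted over the list alone 3 were lower and 1 higher (median -0.14, camera adjusted p = 0.0109, adjusted p = 0.0447 with an estimated correlation). The estimated call of this list ended without EV R1881 library 2 (adjusted p = 0.111) or 3 (0.0612) or 3A R1881 library 1 (0.131) or 3 (0.0882). Both calls ended with the GC and length correction (median -0.07, camera adjusted p = 0.0541, adjusted p = 0.12 with an estimated correlation). Of 10 named genes 9 kept their call without any 1 library (not STC1), among them PSENEN and ALDOA, which share exon bases with other genes and are uncertain. Replicate numbers paired the libraries here, and with a replicate block 1252 genes were higher and 1157 lower. The mitochondrially encoded mRNAs then passed as higher (camera adjusted p = 0.0281 with the block and 0.196 without), but not with an estimated correlation (adjusted p = 0.699 with the block and 0.756 without). The total of 1451 was 867 without EV R1881 library 2, 822 without EV R1881 library 3 and 813 without 3A R1881 library 3. With the GC and length correction 1042 of the 1451 genes kept their call.

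**Figure D3:**
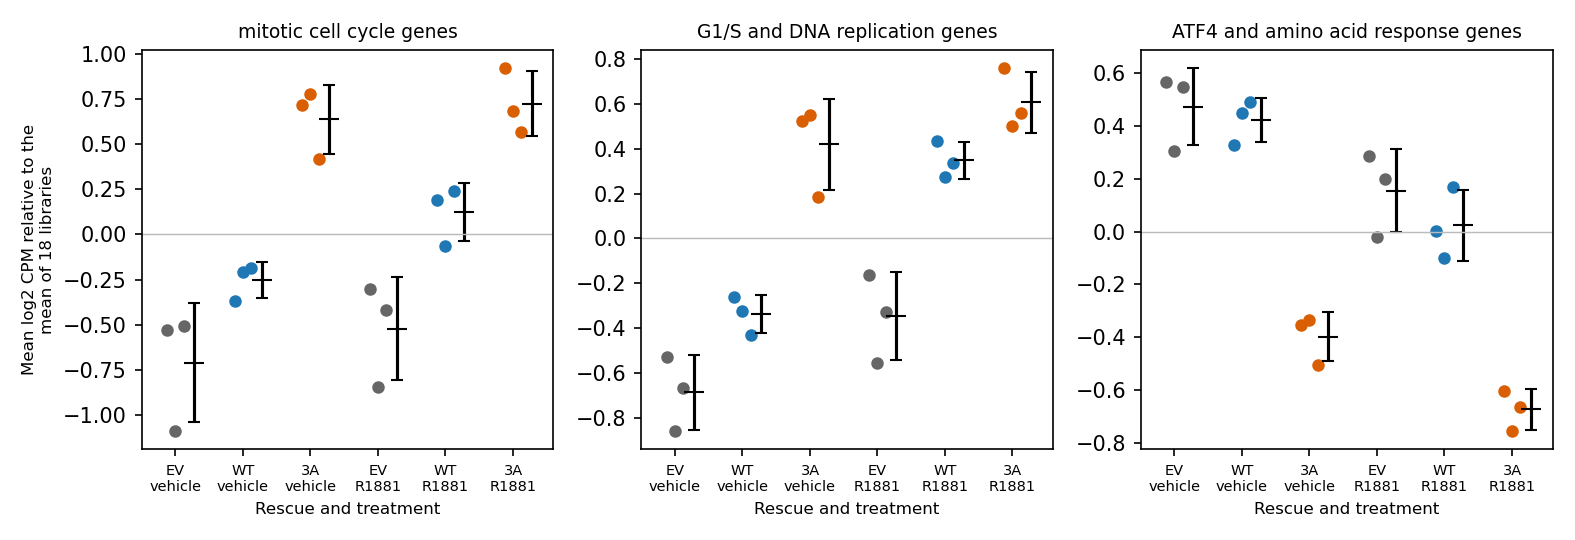
Scores of mitotic cell cycle genes, G1/S and DNA replication genes, and ATF4 and amino acid response genes in each library (points), each score being the mean over members of log2 CPM minus the member's mean over the 18 libraries, with the group mean (horizontal mark) and SD (error bar, n = 3). In 3A against EV the list medians are 1.34, 1.18 and -0.91 in vehicle and 1.28, 0.98 and -0.81 with R1881.

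The direct comparison of the 3A mutant with wild-type HOXB13 asks what the loss of the phosphorylation sites changes. In vehicle, CD55, the complement decay-accelerating factor, went from 34.7 ± 3.20 CPM in WT to 6.74 ± 1.0 in 3A (-2.36 ± 0.17, edgeR adjusted p = 1.54e-07). LCN2 fell by 2.77 ± 0.33, edgeR adjusted p = 3.93e-05, and BVES, OR51E2 and TGFB3 stood at -2.29, -2.09 and -2.07. GPR1 (-2.84), KLHDC7B (-2.82), C1orf158 (-2.35) and DMGDH (-2.07, edgeR adjusted p = 0.000120) were also lower. CAMK2N1 was higher, at 103 ± 13.4 CPM in 3A and 34.7 ± 5.04 in WT (1.56 ± 0.28, edgeR adjusted p = 0.00144). TICRR, a regulator of replication origin firing (1.45 ± 0.19, edgeR adjusted p = 7.66e-05), ESPL1, the separase gene (1.39 ± 0.18, edgeR adjusted p = 8.00e-05), and CLSPN (1.34, edgeR adjusted p = 0.000764) were higher too. By edgeR 453 genes were higher and 514 lower in 3A. Of 22 G1/S and DNA replication genes 19 were higher, and 20 when adjusted over the list alone (median 0.81, camera adjusted p = 1.38e-35, adjusted p = 0.0198 with an estimated correlation), with UHRF1 at 1.07, edgeR adjusted p = 3.62e-05. Of 20 mitotic genes 18 were higher, and 20 when adjusted over the list alone (median 0.90, camera adjusted p = 1.90e-33, adjusted p = 0.0207 with an estimated correlation), with CENPF at 1.10, edgeR adjusted p = 4.70e-05 and MKI67 at 1.25. The estimated calls of these lists ended without WT vehicle library 1 (adjusted p = 0.0521 for G1/S and 0.0733 for mitotic genes) or 3A vehicle library 1 (adjusted p = 0.0511 for both). ATF4 and amino acid response genes were lower in 18 of 20 cases, and in 19 when adjusted over the list alone (median -0.81, camera adjusted p = 1.47e-44, adjusted p = 0.00277 with an estimated correlation). TRIB3 (-1.25 ± 0.11, edgeR adjusted p = 1.71e-06), CEBPB (-1.19, edgeR adjusted p = 7.11e-06) and SESN2 (-0.92) are examples. Of 30 androgen-induced genes 4 were higher, and 6 when adjusted over the list alone (median 0.18, camera adjusted p = 0.000610, adjusted p = 0.244 with an estimated correlation). KLK2 was at 1.14, edgeR adjusted p = 0.000651, and the count was 2 without 3A vehicle library 2. Of 15 fatty acid synthesis genes 5 were higher, and 7 when adjusted over the list alone (median 0.34, camera adjusted p = 0.000151, adjusted p = 0.132 with an estimated correlation), and with the GC and length correction the list passed with an estimated correlation (adjusted p = 0.027). The desaturase FADS2 was at 0.63, edgeR adjusted p = 0.00315, and the count was 2 without WT vehicle library 3 or 3A vehicle library 2 or 3. Of 20 named genes 15 kept their call without any 1 library (not AKAP12, HTR5A, SI, PDE4A and POPDC3), among them SRXN1 and ALDOA, which are uncertain because of shared exon bases. The total of 967 was 559 without WT vehicle library 2, 472 without 3A vehicle library 2 and 588 without 3A vehicle library 3, where the split turned to 340 higher and 248 lower. HOXB13 RNA was itself higher in 3A than in WT in these libraries.

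With R1881, 242 genes were higher and 303 lower in 3A than in WT by edgeR. The 3A libraries again had less CD55 (-2.13 ± 0.19, edgeR adjusted p = 2.13e-06), less BVES (-2.40 ± 0.27, edgeR adjusted p = 2.42e-05) and less BCL11B (-2.60 ± 0.32, edgeR adjusted p = 5.31e-05). OR51E2 (-2.28), GRIK1 (-2.24, edgeR adjusted p = 0.00111), DMGDH (-2.16) and AOC1 (-2.02) were lower as well. So were the kinase STK32A (-1.88), the BH3-only gene HRK (-1.83) and the phosphodiesterase PDE2A (-1.82). UGT2B28, of the family that glucuronidates androgens, was higher in 3A (2.38 ± 0.33, edgeR adjusted p = 0.000187), with the reservation that members of that family share sequence. SPDEF (0.83 ± 0.10, edgeR adjusted p = 5.31e-05), KRT8 (0.92, edgeR adjusted p = 6.14e-05) and FKBP5 (0.66, edgeR adjusted p = 0.00113) were higher in 3A, and ACKR3 was lower (-0.95 ± 0.10, edgeR adjusted p = 7.24e-06). ATF4 and amino acid response genes were lower in 14 of 20 cases, and adjusted over the list alone 18 were lower and 1 higher (median -0.78, camera adjusted p = 2.66e-38, adjusted p = 0.00624 with an estimated correlation). The amino acid transporter SLC7A5 (-1.35, edgeR adjusted p = 4.22e-05), SESN2 (-1.01) and TRIB3 (-1.06, edgeR adjusted p = 9.98e-06) are examples. Of 20 mitotic genes 9 were higher, and 18 when adjusted over the list alone (median 0.63, camera adjusted p = 4.54e-19, adjusted p = 0.0861 with an estimated correlation). CENPF was at 0.68, edgeR adjusted p = 0.00451, and the count was 3 without WT R1881 library 2 and 4 without 3A R1881 library 1. For G1/S and DNA replication genes 0 of 22 were called by edgeR, with 7 higher at an unadjusted p under 0.05 and 2 by DESeq2. Adjusted over the list alone 2 were higher (median 0.26, camera adjusted p = 2.80e-06, adjusted p = 0.332 with an estimated correlation). Of 30 androgen-induced genes 7 were higher, and adjusted over the list alone 11 were higher and 1 lower (median 0.22, camera adjusted p = 4.62e-09, adjusted p = 0.0861 with an estimated correlation). The stress gene NDRG1 was at 1.14, edgeR adjusted p = 0.00211, and the count was 3 without WT R1881 library 3 and 4 without 3A R1881 library 1. The list passed with an estimated correlation without WT R1881 library 1 (adjusted p = 0.0419), with the GC and length correction (0.0177) or with a replicate block (0.0143). Of 20 named genes 13 kept their call without any 1 library (not UGT2B11, SERPIND1, ELOVL2, UGT2B10, NBL1, GABARAP and ASB2). MTFP1 and ALDOA, 2 further named rises, share 52.5% and 53.5% of their exon bases with other genes. The split of the calls turned to more higher than lower genes in a fit of only the groups compared (263 higher and 212 lower), with the GC and length correction (589 and 493) and with that correction and a replicate block (980 and 749). The total of 545 was 298 without WT R1881 library 2 and 341 without WT R1881 library 3.

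Whether the response to R1881 itself differed between rescue states was tested by interaction. BVES (-2.85 ± 0.39, edgeR adjusted p = 0.00144) and PREP (-1.28 ± 0.15, edgeR adjusted p = 0.000234) had lower responses in WT than in EV, with BVES going from 91.0 ± 22.6 CPM to 12.6 ± 1.67 in WT and from 2.39 ± 0.996 to 2.35 ± 0.494 in EV. The interaction was positive for PTPRR (2.44 ± 0.23, edgeR adjusted p = 1.60e-05), CBLN2 (1.56 ± 0.20, edgeR adjusted p = 0.000563) and ACKR3 (0.87 ± 0.13, edgeR adjusted p = 0.00558), and for AIDA (1.22) and DGKH, a diacylglycerol kinase (1.20). These 5 genes fell with R1881 in EV and had a smaller fall, or none that was called, in WT. PTPRR went from 17.7 ± 1.24 to 2.64 ± 0.568 CPM in EV and from 18.7 ± 1.15 to 15.2 ± 2.77 in WT, where its change was not called (edgeR adjusted p = 0.182), and AIDA from 328 ± 43.1 to 111 ± 17.7 and from 462 ± 34.1 to 364 ± 44.1, again not called in WT (edgeR adjusted p = 0.0819). FBXO7, an F-box protein (-1.06, edgeR adjusted p = 0.00192), ZYX, the focal adhesion protein zyxin (-0.76, edgeR adjusted p = 0.00558), and TBRG1 (-0.81), which shares exon bases with another gene, had lower responses in WT than in EV. FBXO7 went from 152 ± 20.3 to 73.0 ± 5.12 CPM in WT and from 76.2 ± 6.63 to 76.3 ± 2.39 in EV, while TBRG1 rose in both, from 136 ± 12.4 to 232 ± 21.0 CPM in WT and from 77.3 ± 2.54 to 230 ± 1.22 in EV. Between 3A and WT, ERRFI1, a feedback inhibitor of EGFR (1.10 ± 0.15, edgeR adjusted p = 0.00478), and ODC1, the ornithine decarboxylase gene (0.87 ± 0.13, edgeR adjusted p = 0.01), had higher responses in 3A and kept their calls without any 1 library. No list was called by camera with an estimated correlation in the 3 interactions. The G1/S list had a lower response in 3A than in WT (median log2 fold change -0.49, camera adjusted p = 3.02e-15, adjusted p = 0.228 with an estimated correlation), with 0 of 22 members called by edgeR and 12 lower when adjusted over the list alone. By edgeR 34 genes were called for WT minus EV (13 higher and 21 lower), 2 for 3A minus EV (PTPRR and BVES) and 10 for 3A minus WT (7 higher and 3 lower), and 1676, 1072 and 1642 had an unadjusted p under 0.05. For WT minus EV the count was 17 without EV vehicle library 1, 15 without EV vehicle library 2, 52 without WT vehicle library 1, 21 without WT vehicle library 2, 13 and 17 without EV R1881 libraries 2 and 3, and 16 without WT R1881 library 2. The split turned to 8 higher and 7 lower without EV vehicle library 2, 7 and 6 without EV R1881 library 2, and 9 and 7 without WT R1881 library 2, and was 12 and 12 without WT R1881 library 3. For 3A minus EV it was 0 without EV R1881 library 2, 4 without 3A vehicle library 1, 6 without 3A R1881 library 1, and 1 without EV vehicle library 1 or 3, 3A vehicle library 2 or 3, EV R1881 library 3 or 3A R1881 library 2. For 3A minus EV 3 genes were higher and 6 lower with the GC and length correction and a replicate block, 4 and 2 with the block alone, 15 and 47 without a filter on low counts, and 1 and 5 without 3A R1881 library 1. For 3A minus WT 72 were higher and 106 lower without a filter, and the count was 27 without WT vehicle library 1, 2 without WT vehicle library 2, 4, 4 and 5 without 3A vehicle libraries 1, 2 and 3, 4 and 3 without WT R1881 libraries 2 and 3, and 5, 6 and 4 without 3A R1881 libraries 1, 2 and 3.

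The effect of each rescue was also set side by side between treatments, in libraries that share none. The labels do not say whether each rescue state is 1 line or several. A difference between lines would recur in both treatments, so shared calls do not separate it from the rescue. Of the genes higher in 3A than in EV, 405 were higher in both vehicle and R1881, where independent lists would share 30.0, and 289 were lower in both (22.8 for independent lists), with 0 going opposite ways (52.4 for independent lists). OAS3, a sensor of double-stranded RNA, was among the genes higher in both (1.32, edgeR adjusted p = 3.85e-05 in vehicle). For WT against EV 62 genes were higher in both treatments (5.17 for independent lists), among them BVES, AOC1, CD274 and CBLN2, 13 were lower in both (0.849) and 1 was opposite (5.47). For 3A against WT 80 genes were higher in both (6.39), 129 were lower in both (9.08), among them CD55 and BVES, and 2 were opposite (15.3). Fold changes in vehicle and R1881 correlated across the 17162 genes with Pearson's r of 0.27 for WT against EV, 0.44 for 3A against EV and 0.33 for 3A against WT (Spearman's rho 0.26, 0.46 and 0.30), genes not being independent replicates. WT against EV and 3A against EV share the EV libraries within a treatment. In vehicle 48 genes were higher in both (4.41 for independent lists, 0 in 20 simulations of unchanged groups against those controls), 7 were lower in both and 2 were opposite. With R1881 386 were higher in both (35.1 for independent lists, 0.05 in the simulations), 211 were lower in both (28.2) and 3 were opposite (62.9). The fold changes of the 2 rescues had a covariance of 0.101 in vehicle against 0.0557 simulated (difference 0.0451; r 0.481, simulated 0.496) and of 0.141 with R1881 against 0.0647 (difference 0.0758; r 0.537, simulated 0.518). The 3 controls cannot be split into parts of 2 libraries each, so part of the excess may come from the shared controls. The simulations held no trend with GC content, while with R1881 both comparisons followed it (Spearman's rho -0.486 for WT and -0.45 for 3A). The simulated counts with R1881 are therefore not those that shared controls with such a trend would give.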

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

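The tests of GC content and gene length, of copy number and of construct integration were chosen after the results they bear on were seen. So were those of total HOXB13 RNA and of shared exon bases. Those of library size and of other splits of the libraries were chosen before. The test of chance placement was also fixed before it was run, but it bears on a run of genes picked from the calls.

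Single genes are listed here because the interaction test found that their response to R1881 differed between rescue states (edgeR adjusted p in parentheses). Between WT and EV the differences were 2.44 for PTPRR (1.60e-05), 1.56 for CBLN2 (0.000563), 0.87 for ACKR3 (0.00558), 1.22 for AIDA (0.00558) and 1.20 for DGKH (0.00558). They were -1.28 for PREP (0.000234), -2.85 for BVES (0.00144), -1.06 for FBXO7 (0.00192), -0.76 for ZYX (0.00558) and -0.81 for TBRG1 (0.0064), which shares 34.5% of its exon bases with another gene. All 10 of these kept their call without any 1 library.

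Between 3A and EV, PTPRR differed by 1.53 (edgeR adjusted p = 0.0154) and BVES by -2.95 (edgeR adjusted p = 0.00788). The call of PTPRR was lost without EV vehicle library 1 (1.52) or 3 (1.47), 3A vehicle library 2 (1.44) or 3 (1.48), EV R1881 library 2 (1.43) or 3 (1.44), or 3A R1881 library 2 (1.51), and that of BVES without EV R1881 library 2 (-2.79).

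Between 3A and WT, ERRFI1 (1.10, edgeR adjusted p = 0.00478) and ODC1 (0.87, edgeR adjusted p = 0.01) kept their call without any 1 library. NUCB2 (1.13, edgeR adjusted p = 0.01) lost it without WT vehicle library 2 (1.08). BCAP29 (0.945, edgeR adjusted p = 0.017) lost it without WT vehicle library 2 (0.93), 3A vehicle library 2 (0.90) or 3 (0.85), WT R1881 library 3 (0.89) or 3A R1881 library 3 (0.89). GADD45G (1.11, edgeR adjusted p = 0.0275) lost it without WT vehicle library 2 (1.14), 3A vehicle library 1 (1.0) or 3 (1.13), WT R1881 library 1 (1.08), 2 (1.10) or 3 (1.15), or 3A R1881 library 1 (1.09) or 3 (1.04). SLC29A1 (-0.97, edgeR adjusted p = 0.0249) lost it without WT vehicle library 2 (-0.98), 3A vehicle library 1 (-0.995) or 2 (-0.909), WT R1881 library 2 (-0.901) or 3 (-0.999), or 3A R1881 library 3 (-0.854). CCDC80 (-2.17, edgeR adjusted p = 0.0456) and ACKR3 (-0.72, edgeR adjusted p = 0.0456) lost theirs without any of the 12 libraries but WT vehicle library 1, at -2.06 to -2.27 and -0.68 to -0.77.

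In WT against EV with R1881, 122 of 1194 genes on chromosome 19 were lower and 21 higher, with a median log2 fold change of -0.15. Chromosome 19 genes had a median GC content of 57.3% and those of other chromosomes 48.0%, and with the correction for GC content and gene length the median was -0.0487. A loss of chromosome 19 copies as the whole cause would also lower its zinc finger genes, but those 244 genes had a median of 0.142 (standard error 0.0251), and the other 950 one of -0.21. With the correction these medians were -0.0124 and -0.0673 (standard error of the difference 0.0271), so for the small part of the shift left by it a loss of copies cannot be told apart from an incomplete correction, and the values together are consistent with a trend with GC content behind most of the shift. What made the libraries differ in it stays open, since RNA quality and library preparation were not measured and a biological difference between the rescue states was not tested.

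With an estimated correlation, mitotic and G1/S genes were called higher in 3A than in EV in both treatments and than in WT in vehicle, and ATF4 and amino acid response genes lower in 3A than in EV and than in WT in both treatments. The median of both cell cycle lists in 3A against EV in vehicle was 1.29, against 1.25 with the correction for GC content and length. The ATF4 list in 3A against WT in vehicle moved from -0.815 to -0.784. In these vehicle comparisons a trend with GC content and length accounts for a small part at most. Fold changes there followed GC content only weakly (Spearman's rho -0.095 and 0.0654). With R1881, 3A against EV followed it more (rho -0.45), and corrected medians of these lists are not given here for it. In WT against EV with R1881 (rho -0.486) the mitotic median moved from 0.667 to 0.567 and the G1/S median from 0.713 to 0.683. Thinning the libraries to 1 size (1.29 and -0.81) could not test library size. Fold changes were already scaled by it, and the mean totals of the vehicle groups compared differed by a factor of at most 1.12. A higher total of HOXB13 RNA does not account for the cell cycle genes of WT with R1881. Its log2 fold change against EV had an upper 95% bound of -0.0341 there, while 21 of 22 G1/S genes were higher. An effect of a lower total was not tested. A higher total stays open for 3A, where HOXB13 RNA was higher than in EV and in WT in vehicle (0.51 and 0.50, edgeR adjusted p = 0.00482 and 0.00807) and at 0.283 against EV with R1881 (edgeR adjusted p = 0.119). The level of HOXB13 in 3A, the mutated sites, the growth state of the cultures when collected, and differences between separately made lines may each contribute. The design ties them all to the rescue state, so no test here separates them.

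BVES, POPDC3 and PREP are neighbours on chromosome 6 and were all higher in WT than in EV in vehicle, though POPDC3 had a mean of only 0.46 CPM in EV and 2.41 in WT. At most 1.39% of their exon bases are shared with another gene, so shared reads do not account for them well. A run of 3 neighbours among the higher genes came up in a share of 0.0058 of 10000 random placements. That share cannot settle chance placement, since the run was picked from these same calls. The run also rests on the call of POPDC3, which was lost without EV vehicle library 3 (2.25) or WT vehicle library 2 (1.99). A gain of copies would persist with R1881, but the difference fell with it. The interaction was -1.28 for PREP and -2.85 for BVES (edgeR adjusted p = 0.000234 and 0.00144). The next tested genes outward, HACE1 (0.07) and ATG5 (0.11), were not called, but a smaller gain could miss them. An integration of the construct near the locus in the WT cells alone would leave 3A at the level of EV, so it is not the whole cause, since in 3A against EV in vehicle BVES was at 2.98 and PREP at 0.685 (edgeR adjusted p = 8.27e-07 and 0.000142), with POPDC3 at 0.45 (edgeR adjusted p = 0.633). A regulatory effect of the rescue on this locus is a hypothesis that may fit, and differences between separately made lines stay open, since binding, chromatin and integration sites were not analysed here.

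Each comparison of 2 groups allows 10 splits of its 6 libraries, too few for a share under 0.05, and only the real split gave as many genes. The real counts, with the highest of the other splits, were 132 (1), 1493 (0), 1244 (0), 1451 (0), 967 (0) and 545 (1) for WT against EV, 3A against EV and 3A against WT, in vehicle and R1881 by turns. They were 4336 (0), 3450 (1) and 4202 (0) for R1881 in EV, WT and 3A. By number of lists called, again with too few splits, 1 of 10 splits gave as many for WT against EV in vehicle (5, highest other 4), 5 with R1881 (6, highest other 10), 2 for 3A against EV in vehicle (7, highest other 7) and 7 with R1881 (6, highest other 8). It was 1 for 3A against WT in vehicle (8, highest other 7) and with R1881 (9, highest other 6), and 3 (8, highest other 10), 1 (10, highest other 9) and 9 (5, highest other 9) for R1881 in EV, WT and 3A.

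For the interactions, 100 splits were drawn, and chance cannot be excluded. As many genes were called in 7 of 100 splits for WT and EV (34, highest other 1987), 11 for 3A and EV (2, highest other 3014) and 11 for 3A and WT (10, highest other 517). As many lists were called in 17 (7, highest other 10), 63 (4, highest other 8) and 66 (4, highest other 9). The other splits with as many genes were mostly uneven in the number of libraries left in their own group. That number differed between vehicle and R1881 by 4 or more in 6 of 6, 10 of 10 and 9 of 10 of them. Such a split moves the difference between rescue states into the interaction, so shares over all 100 do not measure chance alone. The number differed by less than 4 in 88, 89 and 88 splits, of which 0, 0 and 1 gave as many genes by edgeR. It differed by 2 in 47, 49 and 50, with highest counts of 4, 1 and 17. In the other 41, 40 and 38 it did not differ, and 0 genes were called. Mixing rescue states or treatments adds spread that can hide calls, so low counts here and above do not measure chance.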

How the results depend on the processing

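The corrections for GC content and gene length, alone, with the replicate block and with an estimated correlation, and the block with an estimated correlation, were chosen after the results had been seen. The cause was not tested for any change given here. No result changed direction while called under any alternative. The median log2 fold change of all genes stayed within 0.1 of 0 under each scaling, the farthest being -0.026 for R1881 in WT. Scaling itself brings the fold changes near 0, so this does not test for a shift of all genes. Depth limits mainly genes of low count.

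Replicate numbers paired the libraries by the stated rule in 2 comparisons only. WT against EV with R1881 missed that rule narrowly (0.0986, 0.121 and 0.158). Every library also correlated best with its own number in WT against EV with R1881 and in 3A against WT in both treatments. Mitochondrially encoded RNA took its smallest share of the counts in library 1 of every group. With R1881 in WT it was 2.71%, 4.77% and 4.30% in libraries 1, 2 and 3. The numbers may therefore mark an order or batch that the groups share, and the labels do not say so. With the replicate block the counts of called genes were 270 and 2709 for WT against EV (vehicle, then R1881), 2072 and 2409 for 3A against EV, 1732 and 1046 for 3A against WT, and 133, 6 and 96 for the differences in response between WT and EV, 3A and EV, and 3A and WT. With the block and the GC and length correction they were 325 for WT against EV in vehicle, 2592 and 2212 for 3A against EV, 2271 and 1729 for 3A against WT, and 249, 9 and 225 for the 3 differences. The block ended the call of none of 496 results for single genes. In the paired comparisons it changed no other call of HOXB13 or of a list than that of the mitochondrially encoded mRNAs in 3A against EV with R1881. In the others it brought camera calls for those mRNAs in WT against EV in vehicle (adjusted p = 0.00613), for ATF4 and amino acid response genes with R1881 in 3A (0.0402) and in the difference of 3A and WT (0.0437), and for ribosome biogenesis genes in that difference (0.0437), and ended that of markers of other cell types in WT against EV in vehicle (0.0541). None of the calls the block brought passed with an estimated correlation (adjusted p = 0.583 and 0.699 for the mitochondrially encoded mRNAs in WT against EV in vehicle and in 3A against EV with R1881, 0.618 and 0.685 for ATF4 genes, 0.554 for ribosome biogenesis genes).

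With the GC and length correction alone, counts were 1524 and 1082 for 3A against WT and 94 and 63 for the differences between WT and EV and between 3A and WT. DESeq2 called 236 for WT against EV in vehicle, 893 for 3A against WT with R1881, and 151, 8 and 81 for the 3 differences. Without a filter on low counts there were 325, 869, 226, 62 and 178 in the same order. Fits of only the groups compared gave 64 and 2366 for WT against EV, 527 for 3A against WT in vehicle, and 21, 7 and 2 for the differences. Limma on log2(FPKM + 1) gave 53 for WT and EV.

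Without 1 library, counts were 66 to 187 and 601 to 1754 for WT against EV, 751 to 1100 and 813 to 1427 for 3A against EV, 472 to 1295 and 298 to 441 for 3A against WT, 3433 to 3953, 2477 to 3536 and 3290 to 4021 for R1881 in EV, WT and 3A, and 13 to 52, 0 to 6 and 2 to 27 for the 3 differences. HOXB13 in 3A against EV with R1881 passed with the correction, at 0.38 alone and 0.376 with the block. Without 1 library HOXB13 was at 0.39 to 0.59 in 3A against WT in vehicle, 0.44 to 0.64 with R1881, and -0.39 to -0.30 for R1881 in EV.

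Of 79 list calls by camera, 26 passed with an estimated correlation. With that and the GC and length correction 31 lists were called. Of these 6 were not among the 26, namely androgen-induced, G1/S and unfolded protein response genes in WT against EV with R1881, fatty acid synthesis genes in 3A against WT in both treatments and androgen-induced genes in 3A against WT with R1881, while luminal epithelial genes in 3A against EV with R1881 lost their call (adjusted p = 0.12). With an estimated correlation and the block 29 were called, the further 3 being androgen-induced and G1/S genes in WT against EV with R1881 (adjusted p = 0.0202 for each) and androgen-induced genes in 3A against WT with R1881 (0.0143). At the preset correlation the correction brought calls for mitochondrially encoded mRNAs in WT against EV in vehicle (camera adjusted p = 0.0312), fatty acid synthesis genes in WT against EV with R1881 (0.0103), HOXB cluster neighbours with R1881 in EV (0.039), and androgen-induced and ribosome biogenesis genes in the difference of 3A and WT (0.0336 and 0.00712), none of which passed with an estimated correlation (adjusted p = 0.612, 0.0811, 0.168, 0.49 and 0.49 in that order). It ended those of luminal epithelial genes in 3A against EV with R1881 (0.0541) and in the difference of WT and EV (0.077), of G1/S genes in that of 3A and EV (0.0625) and of mitochondrially encoded mRNAs in that of 3A and WT (0.236). By fry, 0 lists were called for WT against EV in vehicle and for each of the 3 differences, where camera with the preset correlation called 5, 7, 4 and 4. Of the 496 gene results, the call was lost in 53 by limma, 17 with the correction, 17 without a filter, 8 by DESeq2, 6 with the correction and the block, 2 with RLE factors and 1 among protein-coding genes only, and 130 lost it without some 1 library. It was lost in 44 of the 492 with a value in fits of only the groups compared, and in 2 of 493 with a filter of 1 CPM.

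With a filter of 1 CPM, Pearson's r between treatments was 0.349, 0.607 and 0.446 for WT against EV, 3A against EV and 3A against WT, and Spearman's rho 0.552 for 3A against EV. With the GC and length correction rho was 0.206 for WT against EV, 22 genes were lower in both treatments there, and 209 were higher and 229 lower in both for 3A against WT. Of genes shared by WT and 3A against EV at an adjusted p under 0.01, 20 were higher and 0 lower in vehicle by edgeR (7 lower at 0.05), and 151 higher and 50 lower with R1881. With the correction 13 were lower in both in vehicle.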

Other observations

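Glycolysis genes were higher in 3A by camera, but none of the 4 calls held with an estimated correlation. Against EV in vehicle 4 of 18 were higher, and 9 when adjusted over the list alone (median 0.26, camera adjusted p = 2.95e-06, adjusted p = 0.231 with an estimated correlation), and with R1881 it was 3, and 9 when adjusted over the list alone (median 0.24, camera adjusted p = 0.000856, adjusted p = 0.511 with an estimated correlation). Against WT in vehicle 5 were higher, and 14 when adjusted over the list alone (median 0.28, camera adjusted p = 6.92e-09, adjusted p = 0.135 with an estimated correlation), and with R1881 it was 4, and 9 when adjusted over the list alone (median 0.27, camera adjusted p = 5.58e-09, adjusted p = 0.130 with an estimated correlation). Against EV the vehicle count was 1 without EV vehicle library 1 or 3A vehicle library 2 or 3 and 2 without EV vehicle library 3, and the R1881 count was 1 without EV R1881 library 1 or 3A R1881 library 3 and 8 without 3A R1881 library 1. Against WT the vehicle count was 2 without any 1 WT vehicle library and 1 without 3A vehicle library 2 or 3, and the R1881 count was 2 without WT R1881 library 1 or 3 or 3A R1881 library 2 or 3. R1881 itself raised HK2, a hexokinase, by 0.91 in EV (edgeR adjusted p = 1.91e-05), 0.92 in WT and 0.88 in 3A, and the glucose transporter SLC2A1 by 0.83, 0.77 and 0.75.

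SNAI2, which encodes the transcription factor Slug, rose with R1881 from 0.487 ± 0.159 to 34.3 ± 4.22 CPM in EV, by 6.14 on the log2 scale (edgeR adjusted p = 8.09e-13), and by 6.19 in WT and 5.84 in 3A. TWIST1, another transcription factor of mesenchymal cells, rose by 0.78, 0.84 and 1.09. Of 18 mesenchymal and migration genes 7 were measured. Of these 2 rose in each state, and 2, 1 and 3 fell in EV, WT and 3A, so that the list median (-0.26, -0.25 and -0.18) was negative while the mean (0.64, 0.78 and 0.60) and the direction of the test were positive (camera adjusted p = 0.226, 0.101 and 0.249). For luminal epithelial genes 5 of 15 rose and 6 fell in each state, with negative medians (-0.16, -0.16 and -0.22) and positive means (0.27, 0.11 and 0.20). PRAC1, beside the HOXB cluster, fell by 0.74, 0.89 and 0.73, and HOXB9 fell by 1.17, 0.81 and 0.88. Of 5 measured HOXB cluster neighbours 4 fell in WT, and 4 when adjusted over the list alone (median -0.86, camera adjusted p = 0.00606, adjusted p = 0.161 with an estimated correlation). Of 18 measured interferon-stimulated genes 5, 3 and 4 fell with R1881 in EV, WT and 3A, as many when adjusted over the list alone, and 1 rose in WT (camera adjusted p = 0.192, 0.109 and 0.212). Of 14 neuroendocrine genes 2 were measured, and SYP, the synaptophysin gene, rose in EV by 0.96 (edgeR adjusted p = 0.0199), but was at 0.82, 0.85 and 0.86 and no longer called without EV vehicle library 1, EV vehicle library 2 or EV R1881 library 3.

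Ribosome biogenesis genes were lower in WT than in EV in vehicle by camera, with 0 of 18 called by edgeR, 1 lower at an unadjusted p under 0.05 and 0 by DESeq2 (median -0.10, camera adjusted p = 0.0128, adjusted p = 0.424 with an estimated correlation), and the list was not called without EV vehicle library 1 (camera adjusted p = 0.107) or WT vehicle library 2 (0.1). Mitochondrially encoded mRNAs were higher in 3A than in WT with R1881, with 1 of 13 called, and 1 when adjusted over the list alone (median 0.27, camera adjusted p = 0.0126, adjusted p = 0.655 with an estimated correlation), a call lost without WT R1881 library 1 (camera adjusted p = 0.959) or 3A R1881 library 2 (0.0859) or 3 (0.533). Of 16 markers of other cell types 5 were measured, and VWF, a clotting factor of endothelial cells, was higher in WT than in EV in vehicle (1.31, edgeR adjusted p = 0.000396). It was the 1 member called, and 1 when adjusted over the list alone (median 0.12, camera adjusted p = 0.0423, adjusted p = 0.249 with an estimated correlation). The call of the list was lost without EV vehicle library 1 (camera adjusted p = 0.107) or WT vehicle library 3 (0.329). Androgen-induced genes in 3A against EV with R1881 had a median of 0.06 and a mean of -0.01, with a negative direction of the test (camera adjusted p = 0.671).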
